A study of Microtus ochrogaster with 25 samples.

How the data were processed

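Messenger RNA was measured by sequencing in bulk nucleus accumbens, a region of the ventral striatum, of prairie voles (Microtus ochrogaster). The 25 libraries fell into 4 groups by the treatment and sex given for each sample: MAN0 females (7), MAN0 males (7), MAN1 females (6) and MAN1 males (5). Per the labels' protocols, RNA was isolated with a column kit that takes DNA and RNA from the same tissue, messenger RNA was captured on magnetic beads, and the libraries were made with a kit that marks strand.

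The deposited table held estimated counts per gene for 19648 Ensembl gene identifiers, which the authors made, per the submitters' processing notes, with Trim Galore, MultiQC and kallisto. Versions, the genome build, the annotation release, the strand setting and the way transcript estimates were added up per gene are not given in the sources used here. Kallisto assigns reads to transcripts by pseudoalignment and divides reads that match several transcripts among them, so between 9.11% and 10.1% of the values of a library were not whole numbers. For the same reason, levels of near-identical paralogs and overlapping genes depend on that division and are uncertain. The estimated counts were rounded to whole numbers before any test and carried no scaling for depth.

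The deposited table gave no gene names. The name table at hand, of the RefSeq annotation of assembly MicOch1.0 with 26397 genes, held 0 Ensembl identifiers, and 0 of the deposited identifiers matched it. Genes are therefore given by identifier. A total of 34 gene lists (striatal cell types, receptors, neuropeptides, stress and immune genes among them), the list tests on them, and named genes such as the oxytocin receptor had been fixed before the data were examined and could not be used. The rule for named genes, which asked for a gene symbol, was replaced by the 2 higher and 2 lower genes with the smallest p in the male, the female and the sex comparison. Groups of co-expressed genes, defined from these libraries after the data were seen, took the place of the lists.

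The numbers at the end of the sample titles give a sample-sheet index that starts again at 1 with library 17. Libraries up to 16 were called run 1 (16 libraries, 4 of each group) and the others run 2 (9 libraries, 3 MAN0 females, 3 MAN0 males, 2 MAN1 females and 1 MAN1 male). Run was a term in every model unless stated.

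Library totals lay between 19882151 and 32570010 counts. Levels are given as TMM-scaled CPM, counts scaled to a common library total after multiplying each total by its TMM factor. On the same scale, the limit that a count of 0 allows, 3 counts, was worth between 0.0911 and 0.156 CPM in a single library. That floor covers counting error only, since the reads carried no molecular identifiers. Of the 19648 genes, 1038 had 0 counts in every library. The filterByExpr rule of edgeR with a minimum count of 10 kept 14843 genes. No libraries were identical, and the 67 pairs of libraries within a group differed by at least 11 times the sampling noise (chi-square per degree of freedom). Nothing in the labels says that libraries of a group came from separate animals or litters, so p-values measure the spread between these libraries.

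Gene tests used the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3 with TMM normalization, group means and run in a joint model of all 25 libraries, and Benjamini-Hochberg adjusted p under 0.05 over 14843 genes. The contrasts were MAN1 against MAN0 in males, in females and averaged over sexes, the difference between the male and female contrasts (interaction), and males against females averaged over MAN0 and MAN1. Each fold change has a standard error (SE) derived from its quasi-likelihood F statistic. The main tests, their covariates and most alternatives were set before the data were examined. The procedure was tested on simulated counts with the means, dispersions and library sizes of these libraries, in which 50 genes each were changed by 1.25, 1.5, 2 and 3 times for each contrast. The changed genes were drawn from those with a mean above 1 CPM, so recovery at lower levels was not simulated. Simulated genes varied independently of each other, unlike real ones.

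Co-expression groups came from 12673 genes with a mean log2 CPM above 1 (prior count 2). The 6000 genes whose spread within groups was largest for their level were clustered by average linkage on the correlation of their deviations from the group and run means. Branches at height 0.7 with at least 40 genes gave 8 co-expression groups with 5123 genes. A co-expression group's value in a library was the mean log2 CPM of its genes relative to their means over all libraries. Differences were tested 2-sided by exact permutation of the MAN1 and MAN0 labels within run and sex (280 assignments in males, 700 in females, 196000 for both sexes jointly) and adjusted by Benjamini-Hochberg over the 8 co-expression groups of a contrast. In simulated values with a co-expression group planted at a log2 shift of 1.5 in MAN1 males, 100% of its members were recovered, with a shift of 1.3. Shifts as small as those of the real co-expression groups were not simulated. The genes were chosen for a large spread after the real group means were removed. That spread enters the relabelled differences but not the real ones, which favours differences within the spread.

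Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom 3.58.1, no filter and a stricter filter on low counts, no run term, replicate number as a block, surrogate variables from sva 3.50.0, only the groups compared, each run alone, robust quasi-likelihood, and each library left out in turn. Chosen after the data were seen were the share of counts in the 10 most abundant genes as a covariate, the omission of both MAN0 male 2 and MAN0 female 7, the male and female libraries of a shared number as a block, their summed counts, another height for the co-expression tree, the first component without MAN0 female 7, and the female spread without single libraries. No sample column of the table was left out.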

Results

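Gene expression in the nucleus accumbens was profiled in 25 libraries from prairie voles of both sexes. The early-life environments compared are named MAN0 and MAN1 in the sample labels, which do not define these names. As background, published vole work uses them for how a family was handled soon after birth: MAN0 families were moved without being touched, whereas the parents of MAN1 families were picked up. The groups were 7 MAN0 females, 7 MAN0 males, 6 MAN1 females and 5 MAN1 males. The title of the series names parental care and a male-specific effect, so MAN1 was compared with MAN0 in each sex and the effects in males and females were compared with each other. Library totals lay between 19882151 counts in MAN0 female 7 and 32570010 counts in MAN0 male 5. A library held on average 16570 ± 70.8 genes with a count above 0 in MAN0 females, 16645 ± 115 in MAN0 males, 16573 ± 104 in MAN1 females and 16486 ± 34.3 in MAN1 males (SD).

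The main variation between libraries ran along the level of the most abundant transcripts and a large set of genes that varied with them. The 10 most abundant genes took from 7.38% of the counts in MAN1 female 6 to 17.2% in MAN0 male 2. Of these 10 genes, 9 belonged to co-expression group 2, a set of 1600 genes that varied together across libraries. The mean of group 2 tracked the share of the 10 most abundant genes over all 25 libraries (Pearson r = 0.916, Spearman rho = 0.945). The permutation p was 1e-04 for each, the smallest the permutations can give, and 0.00012 after Benjamini-Hochberg adjustment over the 3 relations computed, each with r and rho. The relation is partly built in, since the share is made of members of that group. It held in run 1 (r = 0.954), in run 2 (r = 0.909), within groups (r = 0.91) and without the 2 libraries farthest from the median share (r = 0.897). Co-expression group 1, the largest with 2248 genes, went the opposite way, with r = -0.719 (permutation p = 5e-04, adjusted p = 5e-04) and rho = -0.932 (permutation p = 1e-04, adjusted p = 0.00012). Its r was -0.739 in run 1, -0.852 in run 2 and -0.887 without those 2 libraries. The first principal component, with 27.8% of the variance, had r = 0.811 and rho = 0.932 with the share (permutation p = 1e-04 and adjusted p = 0.00012 for each). Its r was 0.892 in run 1, 0.847 in run 2 and 0.858 without those 2 libraries. MAN0 female 7 lay farthest out on this component, at 57.33 (next MAN0 male 2 at 27.83) with a share of 12.6%. Computed again without MAN0 female 7, the component had 21% of the variance and r = 0.928 with the share.

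**Figure D1:**
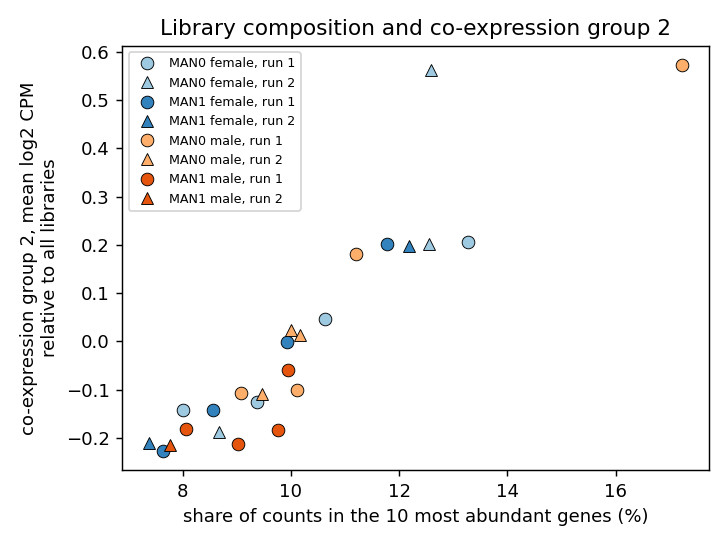
Each point is a library, with the share of its counts in the 10 most abundant genes (percent, horizontal axis) and the mean log2 CPM of co-expression group 2 relative to all libraries (vertical axis). Colours stand for the 4 groups, circles for run 1 and triangles for run 2. The group 2 mean was higher at a higher share (Pearson r = 0.916), and MAN0 male 2 lay farthest to the right at 17.2%.

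In males, co-expression group 2 had the largest mean difference between MAN1 and MAN0 of the 8 co-expression groups. Its mean was -0.17 ± 0.064 (SD, n = 5) in MAN1 males and 0.067 ± 0.25 (n = 7) in MAN0 males on the log2 scale. The estimate was lower in MAN1 males for 1525 of its 1600 genes. Members of a co-expression group were clustered because they varied together. Such counts of members, here and below, therefore largely follow the group mean and are not separate support. The run-adjusted difference of -0.24, or 1.18-fold, did not exceed the spread between libraries (exact permutation p = 0.075, adjusted p = 0.429 over 8 groups). Co-expression group 1 had a mean of 0.14 ± 0.11 in MAN1 males and -0.033 ± 0.15 in MAN0 males. It had 1984 of 2248 genes higher in MAN1 and a difference of 0.16 (exact permutation p = 0.107, adjusted p = 0.429). Beside both co-expression groups stood the share of the 10 most abundant genes, 8.91% ± 0.976 in MAN1 males (n = 5) and 11.04% ± 2.81 in MAN0 males (n = 7). The run-adjusted difference was -2.23 percentage points (exact permutation p = 0.0857). With that share as a covariate the male difference of group 2 was -0.028 (exact permutation p = 0.543) and that of group 1 was -0.0099 (exact permutation p = 0.918). Since 9 of the 10 genes of the share belong to group 2, this covariate takes out much of a group 2 difference of any cause. The adjusted values therefore cannot tell library composition from rearing. Without MAN0 male 2 and MAN0 female 7 the group 2 difference was -0.15 (unadjusted exact permutation p = 0.0214). Without MAN0 male 2 alone it was -0.14, and its unadjusted exact permutation p was not under 0.05. Without MAN0 female 7 alone it was -0.249 (unadjusted exact permutation p = 0.0286). A female library enters the male difference only through the common run term.

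Among single genes, the smallest p among lower ones belonged to ENSMOCG00000012511, at 10.5 ± 1.46 CPM in MAN1 males and 14.6 ± 1.53 CPM in MAN0 males (SD, n = 5 and 7). Its log2 fold change was -0.47 (SE 0.11). ENSMOCG00000002006 had a log2 fold change of -0.46 (SE 0.11), with 27.7 ± 4.41 CPM in MAN1 males and 37.8 ± 3.56 CPM in MAN0 males. ENSMOCG00000009671 had one of 0.77 (SE 0.21), with 6.15 ± 0.667 and 3.52 ± 0.903 CPM, and ENSMOCG00000010681 one of 0.66 (SE 0.18), with 8.33 ± 1.66 and 5.45 ± 0.798 CPM. None of these 4 genes passed in males (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.599 for each). For each of them 5 of 5 MAN1 males lay on the same side of the MAN0 mean, which their choice by smallest p favours. By edgeR 0 of 14843 genes passed in males, and 1089 genes had an unadjusted p under 0.05, of which 354 were higher and 735 lower in MAN1, against 742 genes expected by chance. DESeq2 and limma-voom also called 0 genes, with 1306 and 891 at an unadjusted p under 0.05. The share of those genes that were lower in MAN1 was 67.5% in the main edgeR model, 78.6% with RLE size factors, 77.4% with DESeq2 and 57.5% with limma-voom. It was 50.5% (532 higher, 542 lower) without MAN0 male 2 and MAN0 female 7 and 52.2% with the male libraries fitted alone, so the excess of lower genes was absent in some fits. Their number moved to 423 without MAN0 male 2, 574 without MAN1 male 5, 655 without MAN1 male 4 and 2089 without MAN0 female 7. In counts simulated at this depth and spread, the edgeR test recovered 48% of 1.5-fold and 86% of 2-fold changes in this contrast. The changed genes all had a mean above 1 CPM.

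**Figure D2:**
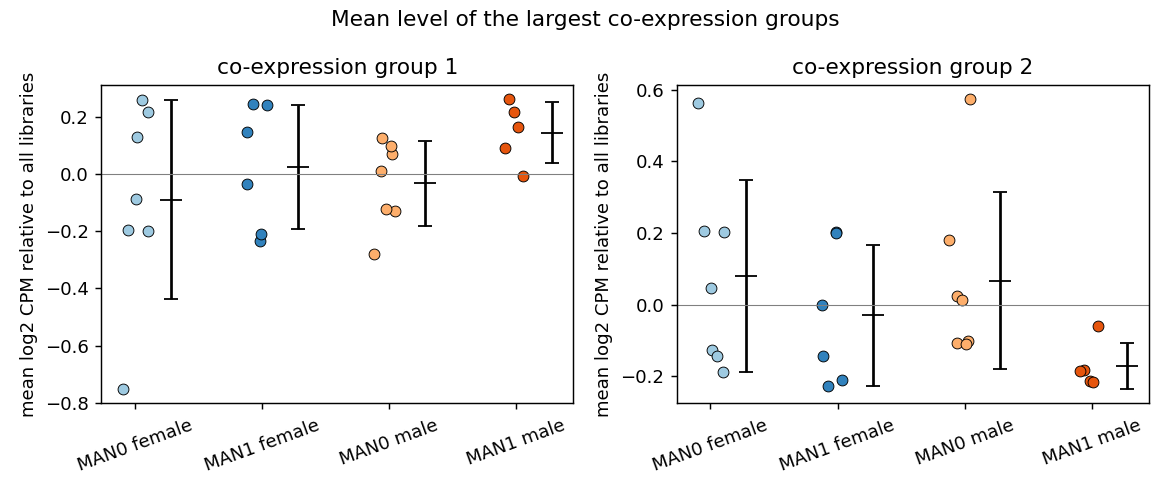
Mean log2 CPM of the genes of co-expression group 1 (left, 2248 genes) and co-expression group 2 (right, 1600 genes) relative to all libraries (vertical axes), by group (horizontal axes); points are libraries and bars the mean ± SD of a group. MAN1 males had means of 0.14 and -0.17 against -0.033 and 0.067 in MAN0 males, differences within the spread between libraries.

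In females, the differences of co-expression groups 1 and 2 had the same sign as in males over all libraries and lay within the spread between libraries. The group 2 mean was -0.03 ± 0.20 (SD, n = 6) in MAN1 females and 0.08 ± 0.27 (n = 7) in MAN0 females. It had 1411 of 1600 genes lower in MAN1 and a difference of -0.11 (exact permutation p = 0.419, adjusted p = 0.862). The group 1 mean was 0.024 ± 0.22 in MAN1 females and -0.091 ± 0.35 in MAN0 females, with a difference of 0.11 (exact permutation p = 0.539, adjusted p = 0.862). Without MAN0 female 7 the differences of groups 2 and 1 were -0.03 and 0.0051, in run 1 alone -0.038 and 0.0041, and in run 2 alone -0.20 and 0.26. The share of the 10 most abundant genes was 9.58% ± 2.07 in MAN1 females and 10.7% ± 2.11 in MAN0 females, a run-adjusted difference of -1.19 percentage points (exact permutation p = 0.336). With that share as a covariate, with the same limit as in males, the female difference of group 2 was 0.0012 and that of group 1 was 0.017. ENSMOCG00000015262 had the smallest p, with 4.86 ± 0.91 CPM in MAN1 females and 7.86 ± 1.22 CPM in MAN0 females and a log2 fold change of -0.70 (SE 0.17). ENSMOCG00000007536 had one of -0.34 (SE 0.087), with 24.3 ± 3.31 and 30.9 ± 2.34 CPM. The 2 higher genes with the smallest p were near the floor of 3 counts: ENSMOCG00000014809 with 0.47 ± 0.20 against 0.139 ± 0.0805 CPM and ENSMOCG00000017369 with 0.552 ± 0.254 against 0.232 ± 0.102 CPM. Their log2 fold changes were 1.71 (SE 0.45) and 1.22 (SE 0.34). All 6 MAN1 females lay on the same side of the MAN0 mean for each of these 4 genes, which their choice by smallest p favours. None passed (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.988). By edgeR 0 of 14843 genes passed in females and 365 had an unadjusted p under 0.05 (157 higher, 208 lower), fewer than the 742 expected by chance. DESeq2 and limma-voom called 0 genes, with 418 and 358 at an unadjusted p under 0.05. The count of 365 moved to 574 without MAN0 female 1 and 615 without MAN0 female 5. The majority turned to higher genes with 2 surrogate variables (293 higher, 186 lower) and without MAN0 female 5 (310 higher, 305 lower). Simulated changes, all in genes with a mean above 1 CPM, were recovered in 64% of cases at 1.5-fold and 90% at 2-fold. In that simulation 5.15% of unchanged genes had an unadjusted p under 0.05, against 2.46% of the real genes, so recovery in the real libraries may be lower.

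The rearing by sex interaction asked whether MAN1 and MAN0 differed by another amount in males than in females, the only comparison that bears on a male-specific effect. For co-expression group 2 the male difference was lower than the female one by a log2 difference of -0.13 (exact permutation p = 0.528, adjusted p = 0.986). For group 1 it was higher by 0.053 (exact permutation p = 0.793, adjusted p = 0.986). No gene passed by edgeR (0 of 14843, smallest Benjamini-Hochberg adjusted p = 1). At an unadjusted p under 0.05 there were 99 genes, 26 higher and 73 lower, against 742 expected by chance. DESeq2 and limma-voom called 0 genes, with 117 and 87 at an unadjusted p under 0.05. Of the 1089 genes with an unadjusted p under 0.05 in males, 1009 (92.7%) had the same sign of difference in females, and of the 365 such genes in females, 315 (86.3%) had it in males. The lists shared 28 higher genes, where independent lists would share 3.74, and 47 lower genes, where independent lists would share 10.3. Genes varied in large sets in these libraries, so independent lists are not what unchanged groups would give, and the overlap and the shared signs were not tested against that. Across 12673 genes the male and female fold changes had r = 0.604, against a median of 0.255 when male and female libraries of a shared number were relabelled together (14 of 700 relabellings as high). It was 0.34 without MAN0 male 2 and MAN0 female 7 and 0.461 with the share covariate. In 34 smaller subsets whose males and females shared no number, r had a median of 0.197 (-0.198 to 0.485). The interaction count moved to 326 without MAN0 female 7 (100 higher, 226 lower). Without MAN0 male 2 and MAN0 female 7 the directions were closer to even (104 higher, 138 lower). The contrast had a median SE of 0.189, against 0.139 in males and 0.13 in females. In simulated counts it recovered 30% of 1.5-fold and 70% of 2-fold differences. There 4.64% of unchanged genes had an unadjusted p under 0.05, against 0.667% of the real genes. The real test gave small p-values less often, so this recovery may not carry over to it.

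Averaged over the sexes, MAN1 libraries had lower values of co-expression group 2 by a log2 difference of -0.17, with 1512 of 1600 genes lower. Values of group 1 were higher by 0.14, with 1970 of 2248 genes higher. Neither exceeded the spread between libraries (exact permutation p = 0.0709 and 0.164, adjusted p = 0.388 for each). Those permutations relabelled the sexes independently. With male and female libraries of a shared number relabelled together, the unadjusted exact permutation p was 0.0557 for group 2 and 0.206 for group 1. The edgeR contrast treated such libraries as independent. Among single genes, ENSMOCG00000012511 had the smallest p, with a log2 fold change of -0.41 (SE 0.078) and an edgeR quasi-likelihood, Benjamini-Hochberg adjusted p of 0.28. By edgeR 0 of 14843 genes passed, and 1776 had an unadjusted p under 0.05, with 752 higher and 1024 lower in MAN1, against 742 expected by chance. DESeq2 called 9 genes, 1 higher and 8 lower in MAN1, with a smallest adjusted p of 0.00127 and 1980 genes at an unadjusted p under 0.05, whereas limma-voom called 0 with 1674. The majority direction depended on the method, with 66.9% lower with RLE size factors (595 higher, 1201 lower), 48.3% lower with limma-voom (866 higher, 808 lower) and 46.3% lower with 2 surrogate variables (326 higher, 281 lower). The edgeR count of 1776 moved to 1070 without MAN0 male 2 and 1155 without MAN1 male 5. Without MAN0 male 2 and MAN0 female 7 the genes were 508 higher and 562 lower. By edgeR 1 gene passed without MAN1 female 3.

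Males and females differed by a small margin at 2 genes, both lower in males. ENSMOCG00000017535 averaged 34.9 ± 3.8 CPM in 12 males and 47.2 ± 5.6 CPM in 13 females (SD), 1.34-fold lower in males. Its log2 difference was -0.43 (SE 0.061, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.00558). ENSMOCG00000012222 averaged 89 ± 7.73 CPM in males and 117 ± 14.1 CPM in females, 1.30-fold lower in males, with a log2 difference of -0.38 (SE 0.063, edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0226). For both genes all 12 males lay below the female mean, although the ranges overlapped, with a highest male at 41.5 CPM and a lowest female at 33.5 CPM for ENSMOCG00000017535. That female was MAN0 female 7. Apart from it, every female lay above every male of the same rearing for this gene. The higher genes with the smallest p did not pass (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.982 for both). They were ENSMOCG00000001731, at 0.573 ± 0.116 CPM in males and 0.374 ± 0.129 CPM in females, and ENSMOCG00000009264, at 42.3 ± 9.07 and 34.2 ± 3.38 CPM. At an unadjusted p under 0.05 there were 359 genes, 128 higher and 231 lower in males, against 742 expected by chance, and DESeq2 called 3 genes and limma-voom 2. The call of ENSMOCG00000012222 was lost in 10 of the 25 fits that left out a single library, so that 1 gene passed. These were the fits without MAN0 female 2, MAN0 male 4 or 7, MAN1 female 1, 2, 4 or 6 or MAN1 male 2, 4 or 5. With run 2 alone 0 genes passed by edgeR, with 262 at an unadjusted p under 0.05, and with run 1 alone 1 gene, ENSMOCG00000017535. With the male and female libraries of a shared number as a block, a model chosen after the data were seen, both calls were lost (edgeR, 0 genes, smallest Benjamini-Hochberg adjusted p = 0.15, 581 genes at an unadjusted p under 0.05). The log2 differences there were -0.42 (SE 0.063) for ENSMOCG00000017535 and -0.36 (SE 0.066) for ENSMOCG00000012222, about the same as without the block, while the residual degrees of freedom fell from 20 to 10. With the same 24 libraries and no block, ENSMOCG00000012222 did not pass either (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 0.0612). Over 39 alternatives the log2 difference stayed between -0.477 and -0.325 for ENSMOCG00000017535 and between -0.422 and -0.326 for ENSMOCG00000012222. Both calls were kept without MAN0 male 2 and MAN0 female 7 and with the share covariate. The smallest adjusted p there was 4.46e-05 and 3.58e-05 (edgeR quasi-likelihood, Benjamini-Hochberg). The unadjusted count of 359 moved to 572 without MAN0 female 1, 649 without MAN0 female 5 and 976 without MAN0 male 2. With run 1 alone it was 135, and the majority turned to genes higher in males (73 higher, 62 lower).

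**Figure D3:**
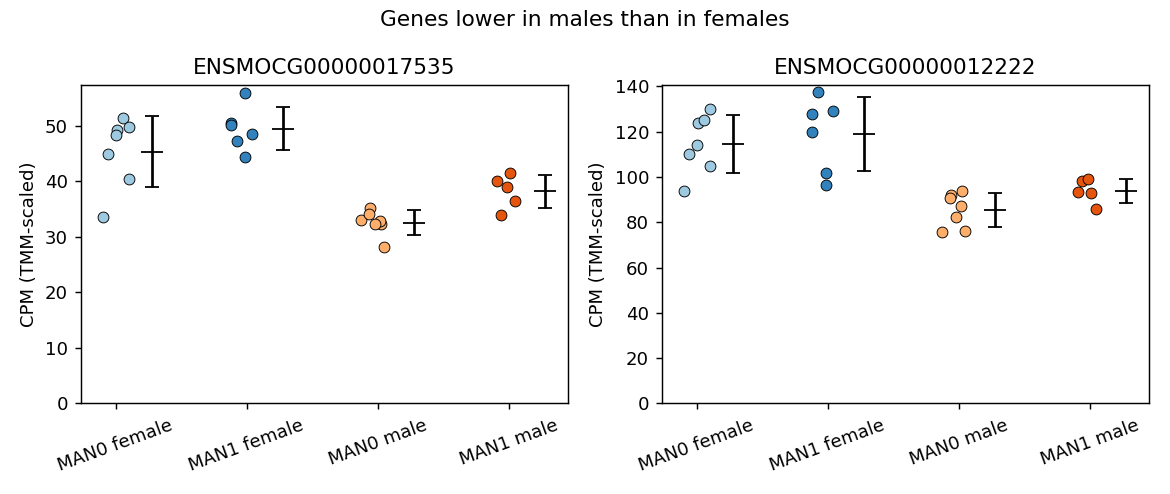
CPM scaled by TMM (vertical axes, from 0) of ENSMOCG00000017535 (left) and ENSMOCG00000012222 (right) by group (horizontal axes); points are libraries and bars the mean ± SD of a group. Males averaged 34.9 and 89 CPM against 47.2 and 117 CPM in females, with overlapping ranges.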

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

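Of what this part reports, the co-expression groups were defined after the data were seen. The tests on other splits and on spread in males were set out before their results were seen. No outcome was set beforehand for the spread in females. A library was set apart where the gap to its nearest neighbour took an unusually large part of its group's range. Of 92 such comparisons, 10 stood apart, where 4.6 would by chance at 1 in 20.

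MAN0 male 2 accounted for 5 of them. The share of its counts in the 10 most abundant genes was 17.22%, with the next MAN0 male at 11.2%. Its co-expression group 2 mean was 0.5724 (next 0.1809), its group 3 mean -0.7102 (next -0.1216) and its group 4 mean 0.7032 (next 0.1174). Its level of ENSMOCG00000017535 was 28.07 CPM (next 32.27 CPM), farther in the direction of lower levels in males. MAN0 female 2, the female library of the same number, stood apart in group 4 too, at 0.3914 (next 0.1077). MAN1 female 6 had 28574498 counts in total (28.57 M), with the next MAN1 female at 24808931 (24.81 M). MAN1 female 1 had 42.34 CPM of ENSMOCG00000009264 (next 35.29 CPM). MAN1 male 2 had a group 2 mean of -0.05974 (next -0.1814), and MAN1 male 1 a group 8 mean of -0.8522 (next -0.04631).

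The numbers of genes at an unadjusted p under 0.05 were set against 80 splits of the libraries into groups of the same sizes, the real one included, with run kept in the edgeR fit. Where male and female libraries of a shared number were moved together, a split held 5 or 6 MAN1 males, since MAN1 female 6 has no partner. In males 11 of 80 splits gave at least the 1089 genes of the real one (highest other 2195). In females 61 of 80 gave at least 365 (highest other 4566), and for the interaction all 80 gave at least 99 (highest other 3967), or 78 of 80 when male and female libraries of a shared number were moved together (highest other 3686). Averaged over sexes, 9 of 80 gave at least 1776 (highest other 3775), and 16 of 80 when male and female libraries of a shared number were moved together (highest other 4173). Chance could not be excluded in any of these comparisons. Splits with several times the real count point to a structure of these libraries other than the rearing labels. Splits that part same-numbered libraries can raise the interaction count, since what such a pair shares cancels in the real grouping. For males against females, 2 of 80 splits gave at least the 2 genes past the adjusted threshold, the real one included (highest other 2). That share was under the 0.05 set beforehand, but 80 splits are too few to exclude chance on it. These splits did not keep male and female libraries of a shared number together, and with such pairs as a block 0 genes passed (edgeR, smallest Benjamini-Hochberg adjusted p = 0.15, 581 genes at an unadjusted p under 0.05). The log2 differences of the 2 genes were -0.423 (SE 0.0627) and -0.362 (SE 0.0657) with the block and -0.426 (SE 0.0613) and -0.383 (SE 0.0631) without it. The calls ended with fewer residual degrees of freedom (10 against 20) at about the same fold and SE, and for ENSMOCG00000012222 already when MAN1 female 6 was left out.

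The spread between libraries was lower in MAN1 males than in MAN0 males, with a median variance ratio of 0.561 over 12673 genes. In both sexes these variances were taken within groups with no run term. Run 2 held 1 of 5 MAN1 males and 3 of 7 MAN0 males, so the ratio was not freed of differences between runs. The tables argue against library depth as the source, since in the 5010 genes with a mean count over 1000, where counting noise is small, the ratio was 0.412. Without MAN0 male 2 the ratio was 0.907, so that library alone could account for most of the difference in males. The ratio of MAN1 females to MAN0 females was 0.668 (exact permutation p = 0.733, 700 assignments). It was 1.01 without MAN0 female 7 and between 0.6 and 0.711 without any other female library. Chance assignment of the male libraries stays open as well (exact permutation p = 0.411, 280 assignments). A lower spread after MAN1 rearing was not seen apart from these 2 libraries.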

How the results depend on the processing

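Of the alternatives, the share covariate, the omission of 2 libraries, the block of male and female libraries of a shared number, their summed counts and the tests on co-expression groups and fold-change correlation were chosen after the data were seen. The number of genes past the adjusted threshold stayed at 0 in the male, female and interaction comparisons and at 2 in the sex comparison under RLE size factors, limma-voom, both other filters, no run term, robust quasi-likelihood, the share covariate and the omission of MAN0 male 2 and MAN0 female 7, and at 0 in the averaged comparison. DESeq2 called 9 genes in the averaged comparison, where edgeR called 0, and 3 between the sexes. With run 2 alone, where the 1 MAN1 male was assumed to vary like the other groups, the counts were 1 in males, 1 in females, 3 averaged over sexes and 0 between the sexes. Between the sexes 1 gene passed with run 1 alone and 4 with 2 surrogate variables. Leaving out single libraries gave from 1 to 3 genes between the sexes and from 0 to 1 averaged over sexes, the 1 without MAN1 female 3, and 0 in the other comparisons. The single runs held fewer libraries, and the cause of these changes was not tested.

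With replicate number as a replicate block in place of run, 1 gene passed between the sexes and 0 in the other comparisons, and the unadjusted count in males was 707 against 1089 and the averaged one 1056 against 1776. Libraries of different rearing with a shared number did not deviate together on average (mean correlation -0.0147 over 22 pairs). Single pairs went both ways (SD 0.227, from -0.394 to 0.326). In MAN0, 6 of 7 pairs of a female and a male of the same number correlated above 0.1, and in MAN1 3 of 5. The labels do not say what a number marks, so these pairs were an alternative only. With them as a block 0 genes passed between the sexes, at about the same folds.

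The unadjusted count in males was 276 with the share covariate, 374 with 2 surrogate variables, 240 with run 2 alone and 2392 with the male libraries fitted alone. Averaged over sexes it was 584 with the share covariate, 607 with surrogate variables, 870 with summed pairs, 1114 with run 1 alone, 470 with run 2 alone and 1070 without MAN0 male 2 and MAN0 female 7. The interaction count of 99 was 270 with no filter, 230 with surrogate variables, 190 with the paired block, 259 and 195 with each run alone and 242 without those 2 libraries. Single libraries moved the counts to between 423 and 2089 in males, 249 and 615 in females, 82 and 326 for the interaction, 1070 and 2488 averaged and 240 and 976 between the sexes. With the share covariate the male difference of co-expression group 1 turned to -0.00989 and the female difference of group 2 to 0.00119, and the male difference of group 2 was -0.0281 against -0.235 (exact permutation p = 0.543). The share is made mostly of group 2 members, so these values cannot tell library composition from rearing. The male difference of group 2 had an unadjusted exact permutation p under 0.05 in 11 alternatives. These were RLE size factors (0.0464), no run term (0.0357), the fit without those 2 libraries (0.0214) and 8 fits without a single library (0.0286 to 0.0464), MAN0 female 1, 2 or 7, MAN0 male 1, 3, 4 or 5, or MAN1 female 5. The list tests and their alternatives were not run, for lack of gene names. Of simulated 1.5-fold changes 48% were recovered in males and 30% for the interaction, where the real test gave small p-values less often than the simulated one.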

Other observations

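All tests in this part were chosen after the data had been seen. For some, an outcome was set before the result was seen. These were the fold-change correlation with pairs relabelled together, with the share covariate and without 2 libraries, and the same-numbered pairs with the share removed. For neighbouring libraries it was set afterwards, and for the other tests no outcome was set. Beyond the 2 largest, the co-expression groups held 524, 250, 247, 169, 43 and 42 genes. Group 3 (524 genes) had means of 0.14 ± 0.34 in MAN1 males, -0.022 ± 0.33 in MAN0 males, 0.032 ± 0.16 in MAN1 females and -0.10 ± 0.31 in MAN0 females (SD), with rearing differences of 0.16 in males and 0.13 in females. Group 4 (250 genes) had differences of -0.14 in males and -0.09 in females, group 7 (43 genes) -0.15 and -0.15, and group 8 (42 genes) -0.20 and -0.066. None of the 8 exceeded the spread between libraries (smallest exact permutation adjusted p = 0.429 in males and 0.862 in females), nor did any of 12 groups made at tree height 0.6 (smallest adjusted p 0.6 and 0.9). The way the genes were chosen, by their spread within the real groups, favoured this outcome, so it does not show that rearing left them unchanged.

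No gene separated all male from all female libraries. Among all 19648 genes, 0 had every one of the 12 male libraries above every one of the 13 female libraries, and 0 had every male library below every female one, with or without TMM scaling. No gene was counted in all but at most 2 libraries of 1 sex and in at most 2 of the other (0 in each direction). Genes of the Y chromosome and the X-inactivation transcript usually separate the sexes in mammalian tissue. Whether the table holds such genes was not analysed here, so the sex labels were not checked by expression.

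The MAN1 against MAN0 fold changes of males and females, fitted jointly with a common run term, correlated across 12673 genes (r = 0.604, covariance 0.0203, genes not being independent replicates). Moving male and female libraries of a shared number together gave a correlation as high in 14 of 700 splits (0.02), with a median r of 0.255 and a mean covariance of 0.00668. That argues against joint variation of such pairs as the whole cause. In 34 subsets whose males and females shared no number, however, r had a median of 0.197 (-0.198 to 0.485). No outcome had been set for these subsets. They held fewer libraries, so they do not settle how much of the correlation came from shared numbers. The composition of the libraries and a pair of extreme libraries cannot be told apart from a shared response to rearing. With the share of the 10 most abundant genes as a covariate the correlation was 0.461, above the 0.45 set to exclude composition, but not by its spread (0.36 to 0.485 with single libraries left out). Without MAN0 male 2 and MAN0 female 7 it was 0.34, between the values set for either outcome. It was 0.372 without MAN0 female 7, 0.348 in run 1 and 0.42 in run 2, so a response to MAN1 common to both sexes may contribute but was not separated from these.

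Female and male MAN0 libraries of the same number deviated together from their group means, with a mean correlation across genes of 0.297 (0.0408 to 0.584, 7 pairs, exact permutation p = 0.0139 over 144 pairings). In MAN1 the mean was 0.092 (5 pairs, exact permutation p = 0.271 over 48 pairings). On the second principal component, with 13.7% of the variance, MAN0 male 2 (33.36) and MAN0 female 2 (30.41) lay above all other libraries (next 17.88). The tables argue against library composition as the whole cause, since with the share of the 10 most abundant genes removed the MAN0 mean was 0.387 (exact permutation p = 0.00694). A neighbouring place in the library order did not by itself go with joint deviation, since 9 neighbours of different rearing had a mean of -0.0309. This was lower than the mean of the 12 same-numbered pairs of MAN0 and MAN1 (0.212) by 0.243. The SE of 0.101 took pairs that share a library as independent. All 12 same-numbered pairs were neighbours too, so a shared number cannot be told apart from a neighbouring place within a pair. A candidate explanation is that a number marks a shared litter or dissection day, which the labels do not say and which was not tested.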
